A study of Mus musculus with 15 samples.

How the data were processed

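Labelled RNA of 15 samples of sorted mouse CD8 T cells was hybridized to Illumina bead arrays, 1 array per sample, in 5 groups taken from the labels: naive (n = 3), memory (n = 3), tolerant (n = 3), rescued (n = 4) and re-tolerized (n = 2). Per the labels, RNA was isolated with the RNeasy Plus Mini kit, checked by NanoDrop and Bioanalyzer, and labelled with biotin using the Illumina TotalPrep kit. The scanner software and the slide of each array are not given in the sources used here. The deposited non-normalized table holds intensity values of 25697 probes on a linear scale, which the authors neither background-subtracted nor normalized, as array medians differ (58.4 to 75.7) and no array has values near 0. The deposited series matrix holds log2 values that are quantile-normalized intensities without background correction: computed anew from the intensity table, they matched within 5.0e-09 on every array. Neither file gives detection p-values or counts, so the number of arrays limits the precision.

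The intensity table was analysed in R 4.3.3 with limma 3.58.1. Background was corrected with normexp (offset 50), and values were quantile-normalized and put on the log2 scale. Probes were given current symbols through the Entrez ID (23962 probes), the accession (9) or the annotation as it stood (7), and 1719 probes had no symbol and stayed out of the gene tests. Per gene, the probe with the highest mean over all arrays was used. Probes counted as dim unless they lay, on at least 2 arrays, above the 95th percentile of 1325 probes for chemosensory (e.g. olfactory) receptors on the same array, which left 9929 of 16590 genes. No coordinates are given, as no genome build is named for the platform.

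A linear model with 1 mean per group was fitted to all 15 arrays (10 residual degrees of freedom), with moderated statistics (eBayes) and Benjamini-Hochberg adjustment over the tested genes of each comparison, and genes passed at an adjusted p under 0.05. The 6 main comparisons and 2 secondary ones (rescued and re-tolerized against memory) were fixed before the data were examined, as were the gene lists, the alternatives and the rule for naming genes. Each of 23 gene lists was tested with camera (preset correlation 0.01, and again with an estimated correlation), adjusted over the lists of a comparison. The lists were cell cycle, inhibitory receptors, anergy and TCR-induced regulators, cytotoxic and effector molecules, naive and central memory genes, effector transcription factors, cytokine receptors, chemokine receptors and adhesion, NK-type receptors, TCR signalling, interferon-stimulated genes, apoptosis regulators, glycolysis, mitochondrial respiratory chain, cholesterol synthesis, and immediate-early and heat-shock genes. Lists of other cells covered B cell, myeloid, class II, erythroid and platelet, CD4 and regulatory T, and NK and gamma-delta T cell markers, and 1 list held sex-linked genes. Genes that passed in the same direction in tolerant against naive and against memory cells formed the tolerance-associated set, whose median change was tested with fry in the other 5 comparisons and adjusted over them.

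Genes were named by rule: per main comparison up to 8 rises and 8 falls (4 in secondary ones), the largest among genes that passed, whose groups did not overlap and whose names are not provisional. Up to 4 list members of smallest adjusted p were eligible per list, of which the text prints those of smallest adjusted p, with a fixed choice of genes of interest in tolerance. Of that choice, Cd8a was too dim and Cblb had no named probe.

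Replicates share only a number between groups. Between naive and tolerant arrays, group-centred values of the same number correlated across genes (r = 0.11, 0.26 and 0.16), so pairing is possible, not shown. A fit with the number as a block kept all 52 named calls of that comparison.

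Alternatives were cyclic loess or median scaling, the authors' normalized values, a normexp offset of 16 or no background correction, no filter or a stricter filter on dim probes, the mean of all probes of a gene, a 2-fold minimum, only the 2 groups compared, eBayes with trend and robust, array weights, the number as a block, and leaving out each array. Those added after seeing the data were a block for the memory 3 shift, fits within each side of it, myeloid and class II means as covariates, only rescued 3 and 4, a 2-fold set and dim probes at their bounds. The fit was tested on 9929 simulated genes, 200 changed, fewer than passed here. At 2-fold it found 89.6% to 98.5% per comparison, and 2.75% to 6.04% of calls were false. Figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.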

Results

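Transcript levels were measured on Illumina bead arrays in mouse CD8 T cells sorted from spleen, with 1 array per sample and 15 arrays in 5 groups. The cells carried a transgenic receptor for the GAG antigen (TCR-GAG), and Alb:GAG mice express GAG as a self antigen. Naive cells (3 arrays) were CD44-low cells from TCR-GAG mice. Memory cells (3 arrays) were CD44-high cells also sorted on a further marker, taken from B6 recipients at least 2 months after infection with Listeria carrying GAG. Tolerant cells (3 arrays) were CD44-high cells from TCR-GAG×Alb:GAG mice, which meet their antigen as self. Rescued cells (4 arrays) were tolerant cells that had divided in lymphopenic Alb:GAG hosts, taken 20 to 22 days after transfer. Re-tolerized cells (2 arrays) were rescued cells that had become dysfunctional again in lymphoreplete B6 hosts, taken more than 90 days after transfer. The number of arrays, 2 to 4 per group, limits the precision.

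Raw median intensities were 58.4 to 75.7 per array, and 10380 to 12324 probes per array lay above the limit set by probes of chemosensory receptors. Re-tolerized 1 (10380 probes) and rescued 4 (10781 probes) had the fewest. Of 16590 genes with a named probe, 9929 were tested and 6661 were too dim. Differences are given as log2 difference ± standard error (SE) from the limma fit over all arrays, and "rose", "fell" and "passed" mean an adjusted p under 0.05. Where a probe stayed under the limit on every array of a group, that group was set to the limit, or to its own value where higher, and the fold is given as "at least". Gene lists fixed beforehand were tested with camera at a preset correlation, and where a call did not hold with an estimated correlation that p is given too. The labels do not say whether replicate arrays come from separate mice, so p-values measure only the spread between these samples.

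Across the 9929 genes, the lowest Pearson r within a group was 0.993 in naive, 0.992 in tolerant, 0.980 in memory, 0.973 in rescued and 0.984 between the re-tolerized arrays. The lowest r between groups was that of memory with re-tolerized arrays (median 0.935), and the highest median was that of naive with tolerant arrays (0.975). The first principal component held 33.9% and the second 28.01% of the variance. Genes are not independent replicates, so these r values carry no p. Every array had its highest mean r with its own group, and memory 3, whose closest other group was rescued (mean r 0.974), stood apart from memory 1 and memory 2.

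**Figure D1:**
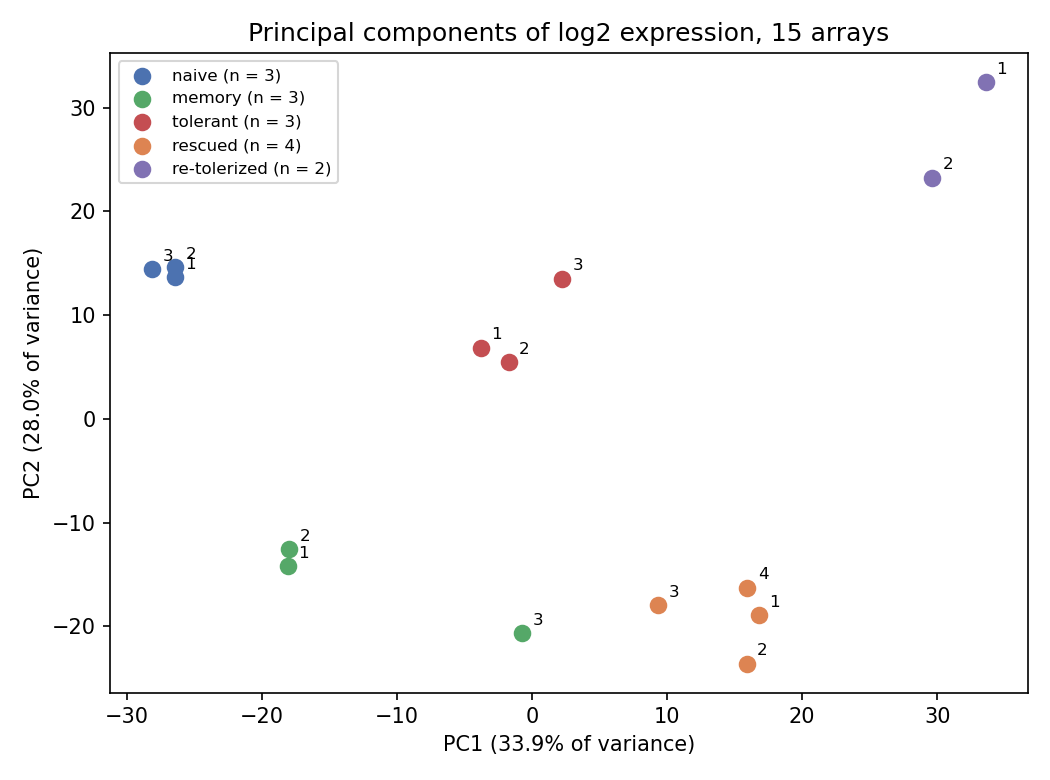
Principal components of the 9929 genes (log2 intensity, centred per gene), with PC1 (33.9% of the variance) on the x axis and PC2 (28.01%) on the y axis, 1 point per array coloured by group. Memory 3 lies away from the other memory arrays on the plot.

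The gene encoding the ankyrin-repeat protein Anks3 differed in memory 3 from memory 1 and 2 by -2.40 on the log2 scale, at the level of the rescued and re-tolerized arrays. Akap8l (-2.18), Hnrnpdl (-1.78) and Sugp2 (-2.01), which encode nuclear proteins, lay there as well, as did Rgl2 (-2.04), a regulator of Ral GTPases, and Dvl1 (-1.76), a Wnt pathway adaptor. In 631 of the 9929 genes, memory 3 lay with all rescued and re-tolerized arrays, beyond all naive, tolerant and other memory arrays, with 109 of them higher and 522 lower in these 7 arrays. With memory 1 or memory 2 in the place of memory 3 there were 20 and 18 such genes. These genes and the 12 plotted ones were singled out after their values were seen. Across genes, the departure of memory 3 from memory 1 and 2 correlated with the difference of rescued from tolerant arrays (r = 0.51) and of re-tolerized from tolerant arrays (r = 0.46), and hardly with re-tolerized minus rescued (r = 0.0199) or tolerant minus naive (r = 0.0818). The comparisons of rescued and of re-tolerized with tolerant arrays cross this shift, and those of tolerant with naive and of re-tolerized with rescued arrays lie on the same side of it. A fit with this split as a block, which rests on memory 3 against memory 1 and 2 and was chosen after seeing the data, is given beside the comparisons it moves.

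**Figure D2:**
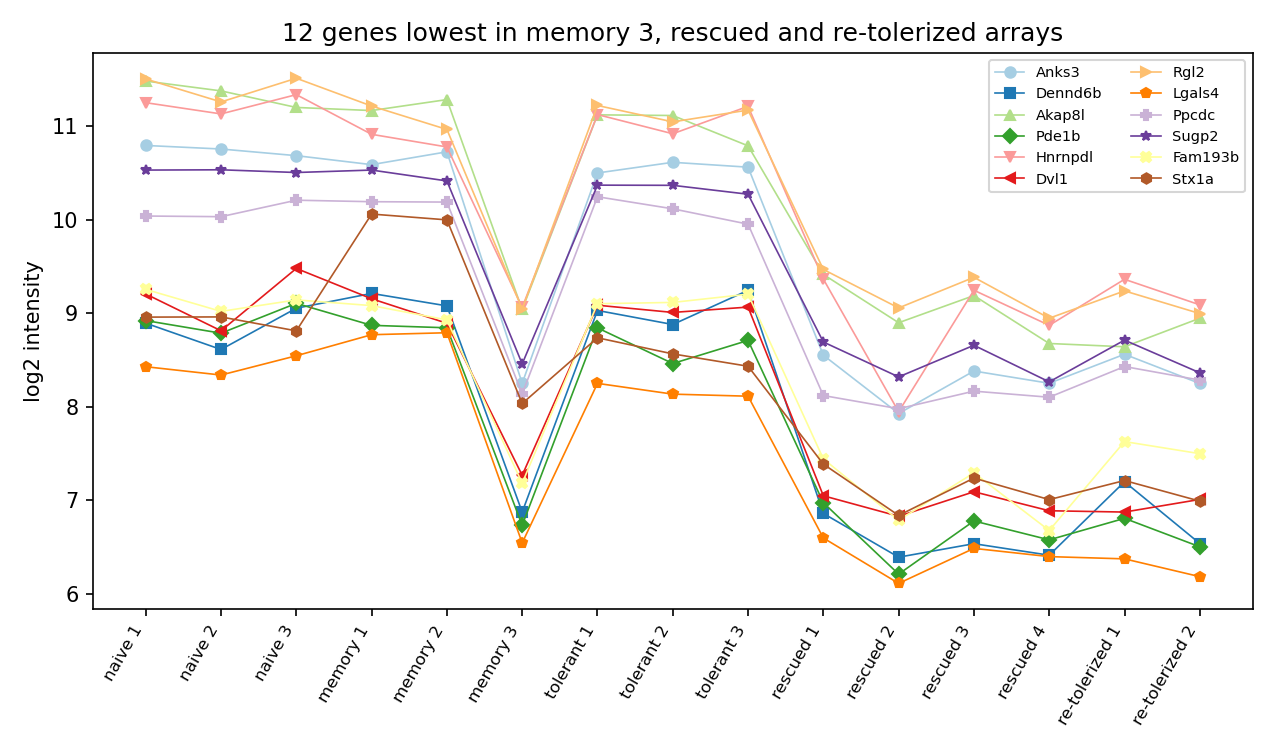
Log2 intensity (y axis) of 12 genes on each of the 15 arrays (x axis), 1 line per gene. Memory 3 lies with the rescued and re-tolerized arrays for each gene, as for Anks3, where it differed from memory 1 and 2 by -2.40 on the log2 scale.

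The comparison of tolerant with naive cells asks how self-tolerant cells differ from cells of the same receptor that have not met their antigen. Ccl5, a T cell chemokine, was the gene that rose most (6.57 ± 0.14, 94.9-fold, n = 3 and 3, adjusted p = 6.2e-13), from a log2 level of 6.98 ± 0.04 to 13.55 ± 0.05 (mean ± SD). Next came Xcl1, a chemokine that draws cross-presenting dendritic cells (4.71 ± 0.18), Cxcr3, a chemokine receptor of effector and memory T cells (4.42 ± 0.13), Anxa2, a membrane-binding annexin (3.97 ± 0.12), and Endod1 (3.36 ± 0.13). The alpha-globin gene Hba-a1 (3.50 ± 0.76) and the histone gene H2ac22 (3.25 ± 0.32) have near-identical paralogs, so which gene their probes read is uncertain. Mcm10, a factor of DNA replication, was below the limit in naive cells and was higher by at least 7.89-fold (log2 3.18 ± 0.19). The largest falls were in Itgae (-3.48 ± 0.39), Actn2 (-3.09 ± 0.16), Gpr83 (-2.25 ± 0.24), Matk (-2.01 ± 0.23), Lrrc75b (-1.99 ± 0.13), Tmie (-1.97 ± 0.21), Slc6a19 (-1.96 ± 0.17) and Ddit4 (-1.91 ± 0.19). Itgae encodes the integrin CD103, which binds E-cadherin, and Ddit4 an inhibitor of mTOR.

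Genes of the cell cycle were higher in tolerant cells: 23 of 27 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 1.41. They included Cdca3 (2.79 ± 0.13), Tk1 (2.42 ± 0.14) and Birc5 (3.05 ± 0.19), of which Birc5 encodes survivin and Tk1 thymidine kinase, and Cdk1, the mitotic kinase (at least 2.56-fold higher, log2 1.62 ± 0.10). The list shifted as a whole (adjusted p = 4.0e-34). Of the cytotoxic and effector molecules, 8 of 19 rose and 0 fell (9 and 0 adjusted over the list alone), among them Ccl4 (2.59 ± 0.26) and Ctsw (1.26 ± 0.14), with adjusted p = 5.6e-08 for the list. Among effector transcription factors, 7 of 15 rose and 1 fell (9 and 1 adjusted over the list alone), led by Tbx21 (T-bet, 2.78 ± 0.16), which directs effector programs, Bhlhe40 (at least 1.80-fold, log2 1.15 ± 0.17) and Gata3 (0.92 ± 0.16), with adjusted p = 5.7e-06. Of the NK-type receptors, 8 of 13 rose and 0 fell (8 and 0 adjusted over the list alone), with Slamf7 (at least 1.61-fold), Klrk1 (NKG2D, at least 1.54-fold) and Klra7 (at least 1.21-fold) above naive levels (adjusted p = 2.5e-07). Of the cytokine receptors, 7 of 19 rose and 1 fell (8 and 2 adjusted over the list alone), with adjusted p = 0.0017 for the list. Among them were Il2rb (1.56 ± 0.13), Il10ra (1.32 ± 0.11), and Il18rap (at least 2.33-fold), subunits of the receptors for IL-2 and IL-15, IL-10 and IL-18.

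Of the inhibitory receptors, 3 of 13 rose and 0 fell (3 and 0 adjusted over the list alone), with adjusted p = 0.0017 for the list and adjusted p = 0.16 with an estimated correlation. Those that rose were Cd160 (1.65 ± 0.12), Tnfrsf9 (1.30 ± 0.27), and Lag3 (at least 3.76-fold, log2 2.12 ± 0.28), which binds class II molecules. Of the anergy and TCR-induced regulators, 6 of 23 rose and 2 fell (7 and 4 adjusted over the list alone), with adjusted p = 0.18 for the list. Rgs1 (1.36 ± 0.14) and Nr4a2 (0.66 ± 0.09) were higher and Dtx1 (-1.39 ± 0.17) and Dusp2 (-0.71 ± 0.10) lower. Apoptosis regulators shifted up (adjusted p = 0.0019): 6 of 21 rose and 2 fell (8 and 2 adjusted over the list alone). Casp1 (1.37 ± 0.16) and Bbc3 (0.99 ± 0.13) were higher and the survival gene Mcl1 lower (-0.70 ± 0.13). Cholesterol synthesis genes shifted down (adjusted p = 3.1e-05): 0 of 15 rose and 5 fell (0 and 7 adjusted over the list alone). Among them were Sqle (-1.19 ± 0.19), squalene epoxidase, and Fdps (-0.57 ± 0.11). Of the naive and central memory genes 5 fell, among them Lef1 (-1.17 ± 0.16), Actn1 (-0.79 ± 0.11) and Ccr7 (-0.86 ± 0.12), and 2 rose, among them Ly6c1 (2.35 ± 0.25), with adjusted p = 0.085. Of the 6 markers of NK and gamma-delta T cells, 5 of which other lists hold, 3 rose (adjusted p = 0.0039, adjusted p = 0.10 with an estimated correlation), and no other list of other cell types passed.

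Among genes of general interest in tolerance, Ifng rose (at least 1.51-fold, log2 0.77 ± 0.13), as did Eomes (1.36 ± 0.35), whose call was lost without each naive array, tolerant 2 or tolerant 3 (adjusted p = 0.055 to 0.080). No difference passed in Pdcd1 (0.22 ± 0.11, adjusted p = 0.26), Ctla4 (0.10 ± 0.21, adjusted p = 0.88), Egr1 (-0.55 ± 0.19, adjusted p = 0.089), Egr2 (-0.55 ± 0.19, adjusted p = 0.084), Tob1 (-0.15 ± 0.10, adjusted p = 0.47) and Il7r (0.41 ± 0.21, adjusted p = 0.28). Egr1 passed without rescued 1 (adjusted p = 0.022). Cd44, used in the sort, was higher (1.59 ± 0.25). In all, 1078 genes passed (638 higher, 440 lower), 255 of them by at least 2-fold, and in 1077 the groups did not overlap, as in 34.9% of all genes (10% by chance). With median scaling the split was 421 higher and 524 lower. Within the 8 arrays on the same side of the memory 3 shift it was 2113.

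The comparison of tolerant with memory cells sets cells that met GAG as self against cells that met it in an infection. Erdr1 rose most (4.45 ± 0.35, 21.8-fold, n = 3 and 3, adjusted p = 1.1e-06), followed by Ppic, which encodes cyclophilin C (3.48 ± 0.14), Xcl1 (3.21 ± 0.18), Dapl1 (2.86 ± 0.35) and the sodium pump subunit Atp1b1 (2.85 ± 0.18). Uhrf1, needed to copy DNA methylation (2.81 ± 0.21), Birc5 (2.77 ± 0.19) and Mcm10 (2.74 ± 0.19) completed the largest rises. Fcmr, the IgM receptor gene of B cells, was below the limit in tolerant cells and lower by at least 17.0-fold (log2 -4.25 ± 0.49). Casp1, the protease that matures IL-1beta, fell by 3.60 ± 0.16, the potassium channel Kcnk5 fell by 2.897 ± 0.11 and Sdcbp2 fell by 2.67 ± 0.10. The class II genes H2-Ab1 (-3.30 ± 0.39), H2-Eb1 (-3.10 ± 0.39) and H2-Aa (-2.84 ± 0.40) and their invariant chain Cd74 (-3.20 ± 0.36) were among the largest falls.

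Cell cycle genes were higher in tolerant cells: 24 of 27 rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 1.36 (adjusted p = 2.9e-33). Examples were Cdca3 (2.28 ± 0.13), Cdk1 (1.45 ± 0.10) and Mcm5 (1.67 ± 0.13), the last a subunit of the replicative helicase. Of the anergy and TCR-induced regulators, 6 of 23 rose and 1 fell (6 and 4 adjusted over the list alone), with adjusted p = 0.032 for the list and adjusted p = 0.16 with an estimated correlation. Those higher included Ndrg1 (at least 3.05-fold), Izumo1r (folate receptor 4, at least 1.68-fold) and Egr1 (1.69 ± 0.19), a transcription factor induced through the T cell receptor. Of the interferon-stimulated genes, 6 of 25 rose and 0 fell (7 and 0 adjusted over the list alone), with adjusted p = 0.024 for the list and adjusted p = 0.49 with an estimated correlation. Examples were Oas2 (1.81 ± 0.15) and Mx2 (0.77 ± 0.17). Cytotoxic and effector molecules shifted down (adjusted p = 0.0030, adjusted p = 0.13 with an estimated correlation): 1 of 19 rose and 6 fell (1 and 7 adjusted over the list alone), with Fasl (-1.66 ± 0.11) and the granzyme genes Gzmm (-1.95 ± 0.23) and Gzmk (lower by at least 2.45-fold) lower. Effector transcription factors shifted down as well (adjusted p = 6.8e-04, adjusted p = 0.099 with an estimated correlation): 1 of 15 rose and 5 fell (1 and 6 adjusted over the list alone). Among them were Rora (-1.06 ± 0.12), Id2 (-1.19 ± 0.24) and Bhlhe40 (-0.78 ± 0.17). Chemokine receptor and adhesion genes shifted down (adjusted p = 4.5e-04, adjusted p = 0.056 with an estimated correlation): 1 of 20 rose and 8 fell (1 and 8 adjusted over the list alone). Among them were Cxcr3 (-1.22 ± 0.13), Itgb1 (-0.80 ± 0.10), and Ccr6 (lower by at least 2.52-fold).

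Of the inhibitory receptors, 4 of 13 rose and 3 fell (4 and 3 adjusted over the list alone), with adjusted p = 0.31 for the list. Higher were Tnfrsf9 (2.24 ± 0.27), Cd5 (1.02 ± 0.12) and Lag3 (at least 3.73-fold, log2 2.09 ± 0.28), and lower was Nrp1 (-1.48 ± 0.20). Cholesterol synthesis genes shifted down (adjusted p = 0.012, adjusted p = 0.19 with an estimated correlation). Sqle was lower (-1.002 ± 0.19). Of the naive and central memory genes, Igfbp4 (2.01 ± 0.24) was higher, with adjusted p = 0.31 for the list. The B cell markers shifted down (adjusted p = 8.2e-11, adjusted p = 0.063 with an estimated correlation): 0 of 10 rose and 9 fell (0 and 9 adjusted over the list alone), with Fcer2a (CD23) lower by at least 2.57-fold and Cd79a, a subunit of the B cell receptor, by at least 3.70-fold. The class II genes, made by antigen-presenting cells, shifted down (adjusted p = 6.5e-07, adjusted p = 0.099 with an estimated correlation): 1 of 8 rose and 7 fell (1 and 7 adjusted over the list alone). These lists and the falls in cytotoxic genes, transcription factors and adhesion genes lie in the same comparison.

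Among other genes of interest, Egr2 (1.27 ± 0.19) rose and Ifng (-1.01 ± 0.13) fell. Tbx21 (-0.60 ± 0.16) lost its call without memory 3, tolerant 1 or tolerant 2 (adjusted p = 0.055 to 0.100). Il7r (-0.70 ± 0.21) lost it without naive 1, each memory array, each tolerant array, rescued 1 or rescued 3 (adjusted p = 0.051 to 0.17). Ctla4 (-0.71 ± 0.21) lost it without naive 1, naive 3, each memory array, tolerant 1, tolerant 2 or rescued 3 (adjusted p = 0.053 to 0.20). No difference passed in Pdcd1 (0.16 ± 0.11, adjusted p = 0.47), Eomes (0.03 ± 0.35, adjusted p = 0.98), Gata3 (-0.38 ± 0.16, adjusted p = 0.17), Tob1 (0.07 ± 0.10, adjusted p = 0.76) and Il2rb (0.34 ± 0.13, adjusted p = 0.13), and Cd44, used in the sort, was lower (-1.11 ± 0.25) except without tolerant 2 (adjusted p = 0.052). Gata3 passed without each re-tolerized array (adjusted p = 0.038) and Il2rb without memory 3 (adjusted p = 0.035). In all, 1061 genes passed (574 higher, 487 lower), 248 by at least 2-fold, and in 1058 the groups did not overlap, as in 29.0% of all genes (10% by chance). The count was 654 without tolerant 3, 1994 with array weights and 409 with the myeloid and class II levels as covariates, and median scaling gave 474 higher and 261 lower. With these covariates 22 of the 47 genes named here that passed kept their call, and Cd79a, Ctla4, H2-Eb1 and Sqle turned positive.

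The comparison of memory with naive cells gives the changes that follow infection and recovery, against which tolerant cells can be set. Ccl5 again rose most (7.25 ± 0.14, 152-fold, n = 3 and 3, adjusted p = 1.5e-13), then Cxcr3 (5.64 ± 0.13), Casp1 (4.97 ± 0.16), the calcium-binding protein gene S100a6 (4.91 ± 0.16) and the glycerol channel Aqp9 (4.31 ± 0.14). Fcmr was below the limit in naive cells and higher by at least 16.9-fold (log2 4.34 ± 0.49), and the class II genes H2-Ab1 (4.30 ± 0.39) and Cd74 (4.08 ± 0.36) were among the largest rises. The largest falls were in Itgae (-4.32 ± 0.39), Erdr1 (-4.17 ± 0.35), Ramp1 (-3.29 ± 0.21), Igfbp4 (-3.27 ± 0.24), Atp1b1 (-3.11 ± 0.18), Dapl1 (-2.92 ± 0.35) and Ampd1 (-2.904 ± 0.22), and Gpr83 was lower by at least 10.3-fold (log2 -3.57 ± 0.24).

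Cytotoxic and effector molecules were higher in memory cells: 12 of 19 rose and 1 fell (13 and 2 adjusted over the list alone), with a median of 0.72 (adjusted p = 2.7e-12). Fasl was higher by at least 4.47-fold, Ifng by at least 3.05-fold (log2 1.78 ± 0.13) and Gzmm by 4.00 ± 0.23 (log2). Of the effector transcription factors, 12 of 15 rose and 0 fell (12 and 0 adjusted over the list alone), with adjusted p = 6.0e-11 for the list. Examples were Tbx21 (3.38 ± 0.16), Gata3 (1.30 ± 0.16), and Bhlhe40 (at least 3.09-fold). Cytokine receptors shifted up (adjusted p = 1.2e-04): 8 of 19 rose and 1 fell (11 and 4 adjusted over the list alone), led by Il10ra (1.69 ± 0.11), Ifngr1 (1.19 ± 0.12), and Il18rap (at least 2.54-fold). Of the chemokine receptors and adhesion molecules, 9 of 20 rose and 3 fell (11 and 3 adjusted over the list alone), among them Cxcr3 (5.64 ± 0.13) and Cxcr5 (1.51 ± 0.15) as rises (adjusted p = 1.1e-04). Of the NK-type receptors, 7 of 13 rose and 0 fell (8 and 0 adjusted over the list alone), with Klrk1 at least 3.27-fold and Slamf7 at least 2.31-fold higher (adjusted p = 4.1e-06). Apoptosis regulators shifted up (adjusted p = 0.0017): 7 of 21 rose and 1 fell (7 and 1 adjusted over the list alone). Casp1, Casp4 (at least 4.197-fold) and Dapk2 (at least 10.4-fold) were higher.

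Naive and central memory genes shifted down (adjusted p = 0.0058, adjusted p = 0.084 with an estimated correlation): 2 of 17 rose and 6 fell (3 and 7 adjusted over the list alone). Igfbp4 (-3.27 ± 0.24), Lef1 (-1.35 ± 0.16) and Dapl1 (-2.92 ± 0.35) were lower and Ly6c1 higher (2.59 ± 0.25). Of the anergy and TCR-induced regulators, 4 of 23 rose and 6 fell (4 and 7 adjusted over the list alone), with adjusted p = 0.19 for the list. Egr1 (-2.24 ± 0.19) and Egr2 (-1.82 ± 0.19) were lower and Rgs1 was higher (1.75 ± 0.14). Of the cell cycle genes, 3 of 27 rose and 0 fell (3 and 0 adjusted over the list alone), with Tk1 higher (0.71 ± 0.14) and adjusted p = 0.068. The mitochondrial respiratory chain shifted up by the list test (adjusted p = 0.039, adjusted p = 0.55 with an estimated correlation) with a median of 0.21, but not with the memory 3 shift as a block (0.07, adjusted p = 0.36). B cell markers shifted up (adjusted p = 3.5e-10): 8 of 10 rose and 0 fell (10 and 0 adjusted over the list alone), with Fcer2a higher by at least 2.55-fold and Cd79a by at least 3.68-fold. The class II genes shifted up (adjusted p = 6.2e-08): 6 of 8 rose and 0 fell (6 and 0 adjusted over the list alone). The myeloid markers shifted up (adjusted p = 0.012, adjusted p = 0.55 with an estimated correlation). The NK and gamma-delta T cell markers shifted up (adjusted p = 0.0021, adjusted p = 0.074 with an estimated correlation). These shifts lie in the same comparison as the cytotoxic, transcription factor and receptor genes above.

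Il2rb (1.23 ± 0.13) and Il7r (1.11 ± 0.21) rose. Ctla4 (0.81 ± 0.21) lost its call without naive 1, naive 3 or memory 2 (adjusted p = 0.062 to 0.071), and Eomes (1.33 ± 0.35) lost it without each naive array or memory 1 (adjusted p = 0.054 to 0.061). The test was not passed by Pdcd1 (0.06 ± 0.11, adjusted p = 0.81) and Tob1 (-0.22 ± 0.10, adjusted p = 0.18), Lag3 was below the limit in both groups, and Cd44 was higher (2.70 ± 0.25). In all, 1329 genes passed (719 higher, 610 lower), 290 by at least 2-fold, and in 1317 the groups did not overlap, as in 33.2% of all genes (10% by chance). The count was 2508 with array weights and 265 with the myeloid and class II covariates, and median scaling gave 376 higher and 889 lower. With the covariates 24 of the 43 named genes that passed kept their call, and Fcmr, Cd79a and Ctla4 turned negative.

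**Figure D3:**
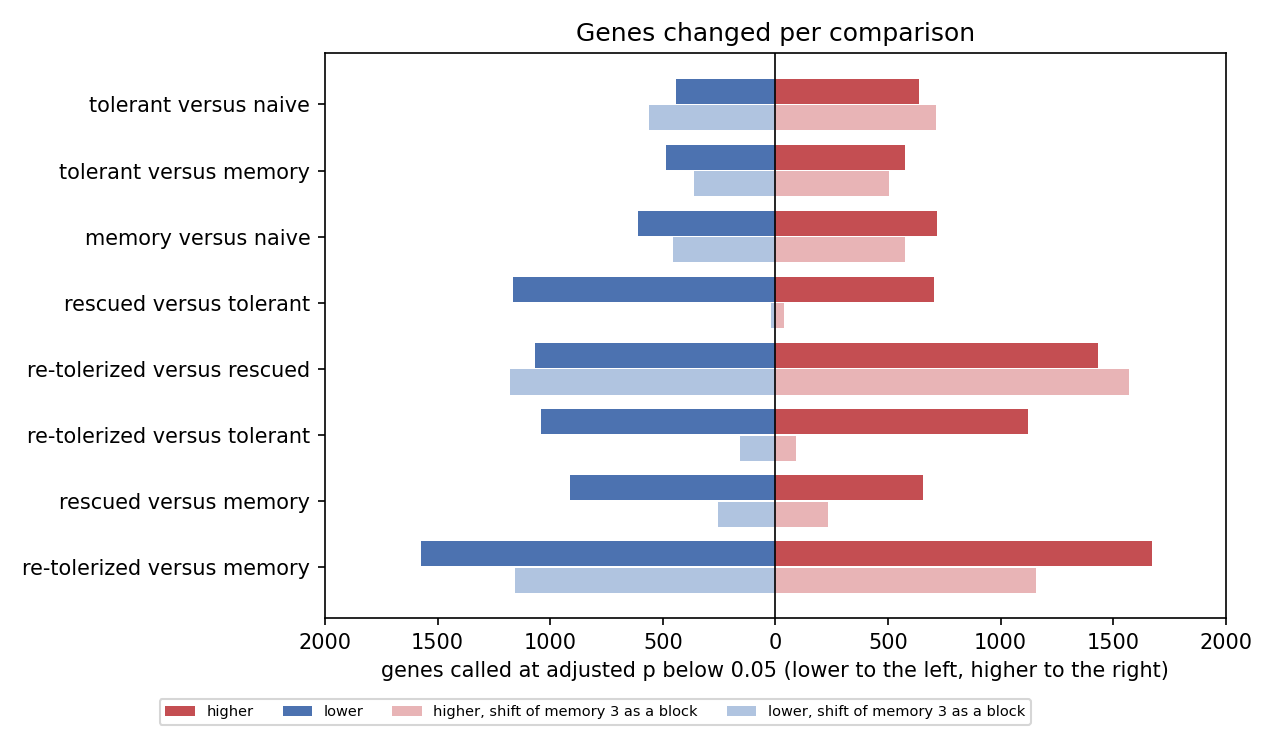
Number of genes that passed per comparison, lower to the left and higher to the right (x axis, genes; y axis, comparison), in dark bars from the fit over all arrays and in pale bars with the memory 3 shift as a block. Rescued versus tolerant arrays went from 1867 genes to 58.

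The comparison of rescued with tolerant cells asks what changes when tolerant cells divide in a lymphopenic host. The largest rises were all in genes of neutrophils and other myeloid cells: Lcn2 (3.56 ± 0.52), S100a8 (3.41 ± 0.58), Ngp (3.10 ± 0.43), Lyz2 (3.02 ± 0.47), Camp (3.00 ± 0.55), S100a9 (2.89 ± 0.63), Ltf (2.88 ± 0.58) and Lyz1 (2.76 ± 0.52) (n = 4 and 3, adjusted p = 3.9e-04 to 0.0056). The largest falls were in Erdr1 (-3.42 ± 0.33), Dennd6b (-2.50 ± 0.41), Anks3 (-2.28 ± 0.42), Hnrnpdl (-2.23 ± 0.38), Rgcc (-2.14 ± 0.18), Fam193b (-2.09 ± 0.34), Dvl1 (-2.09 ± 0.32) and Pde1b (-2.03 ± 0.38). Of these, Anks3, Dennd6b, Hnrnpdl, Dvl1, Fam193b and Pde1b belong to the 12 genes plotted for the memory 3 shift. With that shift as a block, Anks3 was at 0.13 ± 0.24, adjusted p = 0.90 and Pde1b at 0.09 ± 0.30, adjusted p = 0.95, and Rgcc, a regulator of the cell cycle, stayed lower (-2.55 ± 0.32, adjusted p = 0.0026).

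Cell cycle genes shifted down: 0 of 27 rose and 15 fell (0 and 18 adjusted over the list alone), with a median of -0.47 (adjusted p = 9.9e-10, adjusted p = 0.12 with an estimated correlation). Among them were Cdca3 (-1.07 ± 0.12), Tk1 (-0.93 ± 0.13) and Mcm5 (-0.86 ± 0.12), and with the shift as a block the list stayed lower (median -0.65, adjusted p = 6.1e-09, adjusted p = 0.14 with an estimated correlation), while 0 of 27 genes passed. NK-type receptors shifted up: 9 of 13 rose and 0 fell (10 and 0 adjusted over the list alone), with adjusted p = 1.5e-10 for the list. Examples were Klre1 (2.45 ± 0.18), Klra7 (0.93 ± 0.09) and Klrk1 (1.01 ± 0.11). With the block this list stayed higher (median 0.59, adjusted p = 8.3e-11, adjusted p = 0.011 with an estimated correlation), and 2 of 13 genes passed. Of the effector transcription factors, 6 of 15 rose and 0 fell (9 and 0 adjusted over the list alone), with adjusted p = 1.9e-04 for the list and adjusted p = 0.12 with an estimated correlation. Among them were Bhlhe40 (1.12 ± 0.16), Nfil3 (0.87 ± 0.12) and Tbx21 (0.87 ± 0.15). Cytotoxic and effector molecules shifted up (adjusted p = 0.029, adjusted p = 0.20 with an estimated correlation): 5 of 19 rose and 3 fell (5 and 3 adjusted over the list alone). Fasl (1.93 ± 0.11) and Gzmm (2.24 ± 0.22) were higher and Tnf (-1.07 ± 0.16) lower. Chemokine receptor and adhesion genes shifted up (adjusted p = 1.9e-04): 6 of 20 rose and 0 fell (6 and 0 adjusted over the list alone). Examples were Itgb1 (0.71 ± 0.09), S1pr5 (0.76 ± 0.16) and Cxcr3 (0.58 ± 0.12).

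Interferon-stimulated genes shifted up (adjusted p = 5.2e-04, adjusted p = 0.20 with an estimated correlation): 12 of 25 rose and 2 fell (13 and 3 adjusted over the list alone). The guanylate-binding protein Gbp3 (0.89 ± 0.13) and Oas3 (0.59 ± 0.11) were higher and Oas2 lower (-1.55 ± 0.14). With the block this list had a median of 0.14 (adjusted p = 0.022, adjusted p = 0.50 with an estimated correlation) and 0 genes that passed. Apoptosis regulators shifted up (adjusted p = 0.014, adjusted p = 0.12 with an estimated correlation). Dapk2 (1.45 ± 0.10) and Casp1 (1.74 ± 0.15) were higher and Fas lower (-0.64 ± 0.10). The mitochondrial respiratory chain shifted up by the list test (adjusted p = 0.025, adjusted p = 0.47 with an estimated correlation) with a median of 0.20, but not with the block (-0.18, adjusted p = 0.29). Of the anergy and TCR-induced regulators, 4 of 23 rose and 7 fell (4 and 8 adjusted over the list alone), with adjusted p = 0.59 for the list. Nr4a2 (-0.75 ± 0.09) and Rgs16 (-0.94 ± 0.14) were lower and Sla higher (0.56 ± 0.08). Myeloid markers shifted up (adjusted p = 1.5e-10, 0.12 with an estimated correlation): 12 of 16 rose and 0 fell (15 and 0 adjusted over the list alone). Class II genes shifted up (adjusted p = 1.1e-05, 0.12 with an estimated correlation): 6 of 8 rose and 0 fell (7 and 0 adjusted over the list alone). Among them were Cd74 (2.43 ± 0.34) and H2-Ab1 (2.32 ± 0.36). B cell and NK and gamma-delta T cell markers shifted up (adjusted p = 8.1e-04 and 0.0013, with an estimated correlation 0.20 and 0.12). With the block 0 effector transcription factors, chemokine receptor and adhesion genes, myeloid and NK and gamma-delta T cell markers passed. Their lists stayed higher (medians 0.24 to 0.94, adjusted p = 0.10, 0.036, 0.24 and 0.12 with an estimated correlation). With the block 12 lists passed, 4 also with this correlation.

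Egr1 (-1.08 ± 0.18) and Egr2 (-0.81 ± 0.18) fell and Il2rb (0.66 ± 0.12) rose. Ctla4 (-0.62 ± 0.19) lost its call without naive 1, tolerant 2, tolerant 3, rescued 2 or rescued 3 (adjusted p = 0.053 to 0.19). Eomes (1.07 ± 0.32) lost it without each tolerant array, rescued 1, rescued 2 or rescued 3 (adjusted p = 0.052 to 0.13). The test was not passed by Pdcd1 (-0.10 ± 0.10, adjusted p = 0.54), Lag3 (-0.70 ± 0.26, adjusted p = 0.081), Gata3 (0.44 ± 0.15, adjusted p = 0.0504), Ifng (-0.09 ± 0.12, adjusted p = 0.67), Tob1 (-0.11 ± 0.09, adjusted p = 0.47) and Il7r (0.14 ± 0.20, adjusted p = 0.68). Lag3 passed without rescued 1 (adjusted p = 6.1e-04) and Gata3 without memory 3, rescued 4 or each re-tolerized array (adjusted p = 0.0088 to 0.049). Cd44 was higher (0.96 ± 0.24), except without tolerant 1 or tolerant 2 (adjusted p = 0.054 to 0.065). In all, 1867 genes passed (703 higher, 1164 lower), 297 by at least 2-fold, and in 1782 the groups did not overlap, as in 28.7% of all genes (5.71% by chance).

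With the shift as a block, 58 genes passed between rescued and tolerant cells (39 higher, 19 lower). Of the 48 named genes that passed, 7 kept their call and 46 their sign. With larger SEs, which can cost calls, Klre1 (2.38 ± 0.35), Fasl (1.84 ± 0.20) and Casp1 (2.08 ± 0.26) still passed as higher and Rgcc (-2.55 ± 0.32) as lower. The count was 1177 without tolerant 3, 1234 with median scaling and 326 with the myeloid and class II covariates, which kept the call of 14 of the 48 named genes. With these covariates Camp, S100a9 and Ltf turned negative.

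The comparison of re-tolerized with rescued cells asks what changes when rescued cells lose function again. The neuronal growth factor gene Nrn1 rose most (4.74 ± 0.13, 26.6-fold, n = 2 and 4, adjusted p = 1.4e-11), followed by the inhibitory receptor gene Lag3 (3.88 ± 0.30) and Rgcc (3.34 ± 0.20). Rgs16, which turns off G protein signals (3.19 ± 0.16), the tubulin gene Tubb2b (3.12 ± 0.34), the transaminase gene Bcat1 (3.09 ± 0.20), the inhibitory receptor gene Ctla4 (3.09 ± 0.22) and Nrgn (3.08 ± 0.18) completed the largest rises. The largest falls were in Gzmm (-4.37 ± 0.25), Aqp9 (-4.19 ± 0.15), Ly6c1 (-3.98 ± 0.27), Klrd1 (-3.92 ± 0.20), Cxcr3 (-3.76 ± 0.14), Lcn2 (-3.75 ± 0.59), S100a8 (-3.68 ± 0.66) and Lrrk1 (-3.54 ± 0.21). Both groups lie on the same side of the memory 3 shift.

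Cell cycle genes were higher in re-tolerized cells: 25 of 27 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 1.25 (adjusted p = 1.8e-16). Examples were Tk1 (1.74 ± 0.15), Mcm5 (1.67 ± 0.14) and Cdc20 (1.55 ± 0.14). Of the inhibitory receptors, 6 of 13 rose and 0 fell (7 and 0 adjusted over the list alone), with adjusted p = 2.7e-04 for the list and adjusted p = 0.12 with an estimated correlation. Among them were Tnfrsf9 (2.71 ± 0.28) and Nrp1 (2.01 ± 0.22) besides Ctla4 and Lag3. Cytotoxic and effector molecules shifted down (adjusted p = 0.014, adjusted p = 0.17 with an estimated correlation): 5 of 19 rose and 9 fell (6 and 10 adjusted over the list alone). Ccl5 (-3.34 ± 0.15) and Fasl (-2.33 ± 0.12) were lower. Of the cytokine receptors, 1 of 19 rose and 11 fell (2 and 13 adjusted over the list alone), with adjusted p = 8.1e-08 for the list. Ifngr1 (-2.29 ± 0.13), Il10ra (-2.02 ± 0.12) and Il7r (-3.36 ± 0.22) were lower. Of the NK-type receptors, 1 of 13 rose and 10 fell (1 and 10 adjusted over the list alone), with adjusted p = 8.1e-08 for the list. Examples were Klre1 (-2.95 ± 0.21) and Klrk1 (lower by at least 2.97-fold). Of the chemokine receptors and adhesion molecules, 1 of 20 rose and 10 fell (1 and 10 adjusted over the list alone), with adjusted p = 9.9e-06 for the list. Selplg (-1.24 ± 0.10) and Icam1 (-1.23 ± 0.11) were lower.

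Interferon-stimulated genes were lower: 0 of 25 rose and 17 fell (0 and 20 adjusted over the list alone), with adjusted p = 1.2e-11 for the list. Among them were Usp18 (-2.36 ± 0.13), Ifit3 (-2.28 ± 0.21) and Oas3 (-1.09 ± 0.12). Naive and central memory genes shifted down (adjusted p = 2.8e-04): 2 of 17 rose and 9 fell (2 and 10 adjusted over the list alone). The Kruppel-like factor gene Klf3 (-1.77 ± 0.20) and the survival gene Bcl2 (-1.65 ± 0.18) were lower. Of the anergy and TCR-induced regulators, 10 of 23 rose and 5 fell (11 and 5 adjusted over the list alone), with adjusted p = 0.0497 for the list and adjusted p = 0.17 with an estimated correlation. Nr4a2 (1.42 ± 0.10), Izumo1r (1.56 ± 0.11) and Egr2 (2.73 ± 0.20) were higher. Of the effector transcription factors, 4 of 15 rose and 7 fell (4 and 7 adjusted over the list alone), with adjusted p = 0.18 for the list. Tbx21 (-2.80 ± 0.17) was lower and Irf4 (2.08 ± 0.16) and Ikzf2 (Helios, 1.95 ± 0.17) higher. Among the 10 markers of CD4 and regulatory T cells, 4 of 10 rose and 1 fell (5 and 1 adjusted over the list alone), with adjusted p = 0.0045 for the list. Ctla4, Izumo1r and Ikzf2 were higher. Myeloid markers shifted down (adjusted p = 1.2e-07, adjusted p = 0.20 with an estimated correlation): 0 of 16 rose and 12 fell (0 and 12 adjusted over the list alone). Among them were Ngp (-3.08 ± 0.49) and Lyz2 (-3.11 ± 0.53). The NK and gamma-delta T cell markers shifted down (adjusted p = 0.043, adjusted p = 0.21 with an estimated correlation). The class II genes (adjusted p = 0.27) and B cell markers (adjusted p = 0.091) did not pass as lists.

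Egr1 (2.39 ± 0.20) rose in re-tolerized cells, and Eomes (-1.97 ± 0.37), Gata3 (-0.89 ± 0.17) and Il2rb (-1.03 ± 0.14) fell. Tob1 (-0.41 ± 0.10) lost its call without re-tolerized 1 (adjusted p = 0.23). The test was not passed by Pdcd1 (0.25 ± 0.12, adjusted p = 0.14) and Ifng (-0.33 ± 0.14, adjusted p = 0.099) or by Cd44 (-0.45 ± 0.27, adjusted p = 0.27), and Ifng passed without rescued 4 (adjusted p = 0.046). In all, 2497 genes passed (1432 higher, 1065 lower), 595 by at least 2-fold, and in 2415 the groups did not overlap, as in 36.8% of all genes (13.3% by chance). The count was 1420 without re-tolerized 1, which left a lone array assumed to vary like the other groups. It was 1137 with the myeloid and class II covariates, which kept the call of 46 of the 59 named genes that passed.

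**Figure D4:**
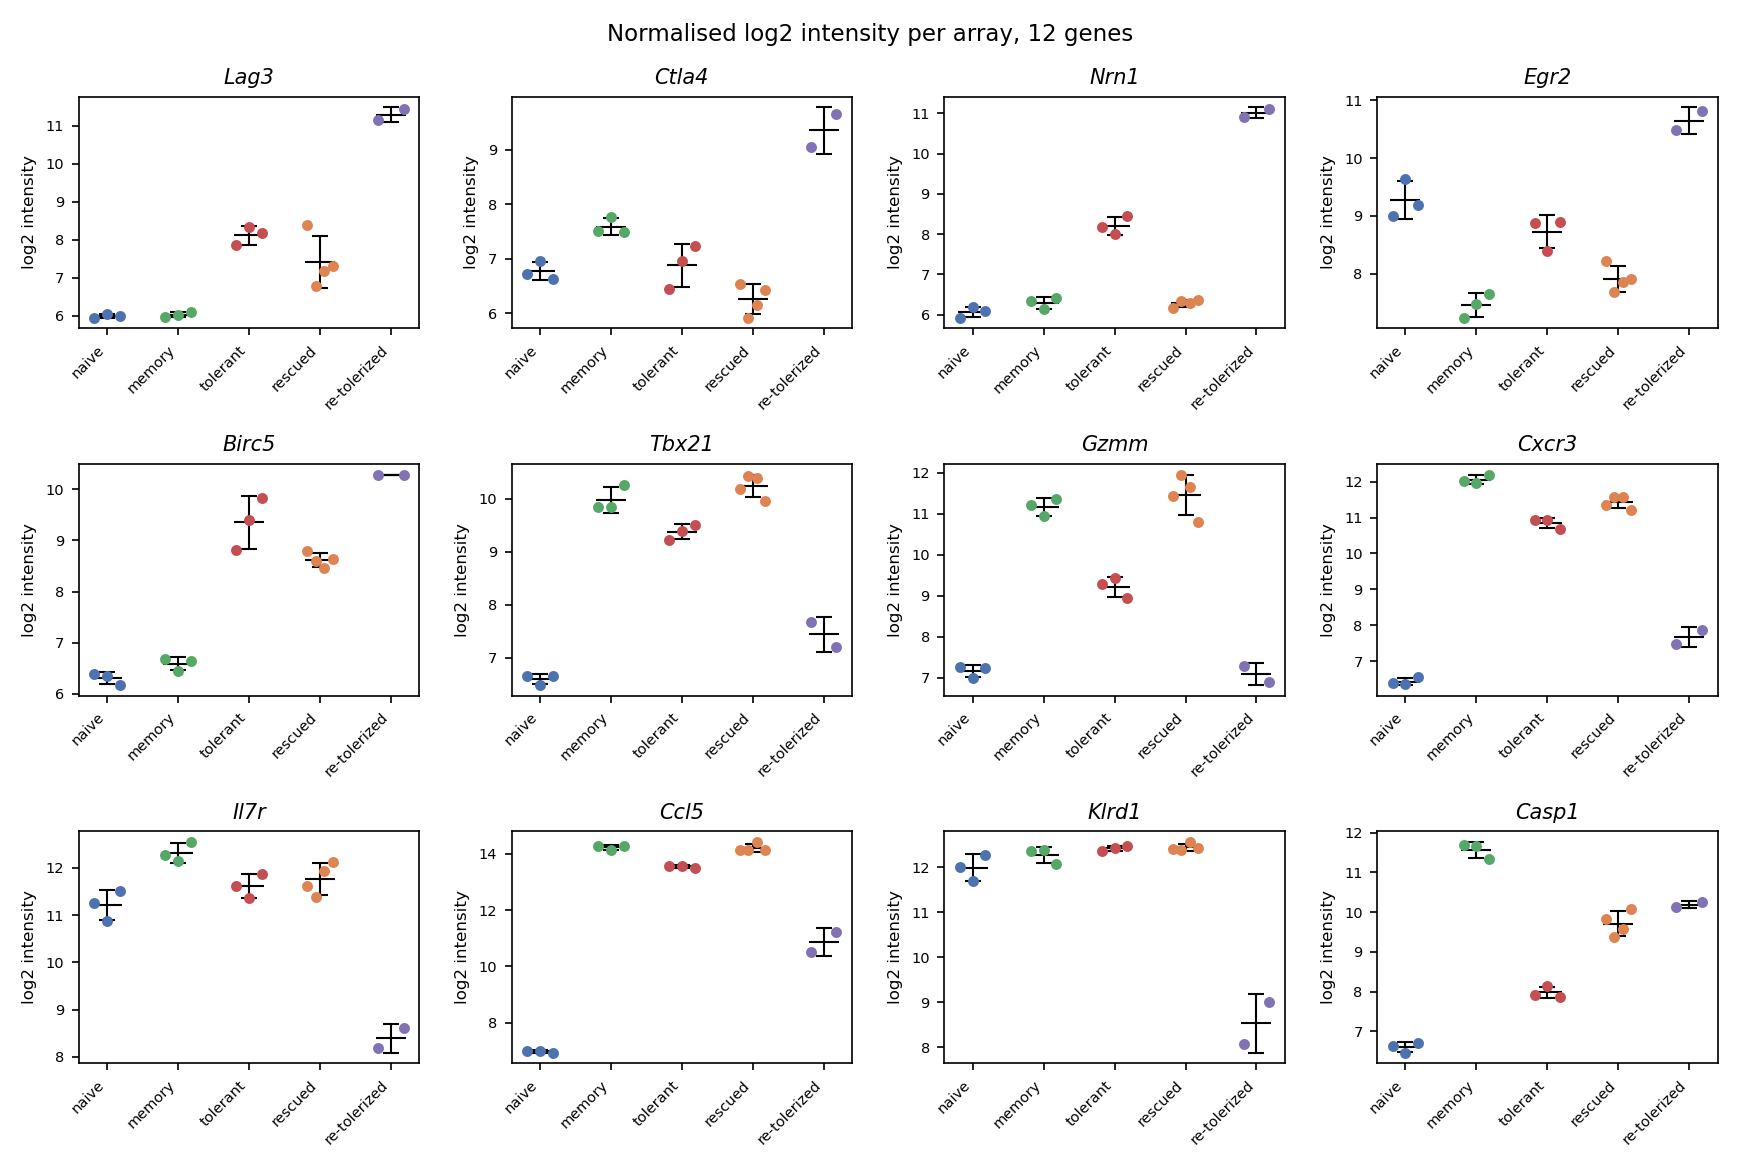
Log2 intensity (y axis) of 12 genes in the 5 groups (x axis), 1 point per array with the group mean and SD. The log2 difference of re-tolerized from rescued arrays was 4.74 for Nrn1 and -4.37 for Gzmm.

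The comparison of re-tolerized with tolerant cells sets the later dysfunctional state beside the earlier state of the same cells. The largest rises were in Lag3 (3.18 ± 0.32, 9.07-fold, n = 2 and 3, adjusted p = 1.4e-05), Nrn1 (2.82 ± 0.13), Ctla4 (2.47 ± 0.23), Cd74 (2.34 ± 0.41), Rgs16 (2.25 ± 0.17), Casp1 (2.21 ± 0.18), Itgae (2.17 ± 0.44) and Irf4 (2.14 ± 0.17). Itgae lost its call without re-tolerized 1 (adjusted p = 0.058). The largest falls were in Il18r1 (-4.00 ± 0.28), Klrd1 (-3.89 ± 0.21), Erdr1 (-3.69 ± 0.39), Ly6c1 (-3.39 ± 0.28), Socs3 (-3.23 ± 0.28), Il7r (-3.22 ± 0.23), Cxcr3 (-3.18 ± 0.15) and Sidt1 (-2.85 ± 0.15). With the memory 3 shift as a block, 246 genes passed (91 higher, 155 lower). Among them were Lag3 (3.08 ± 0.54), Nrn1 (2.64 ± 0.22), Ctla4 (2.63 ± 0.40) and Rgs16 (2.37 ± 0.29) with higher and Klrd1 (-3.59 ± 0.35), Il7r (-3.56 ± 0.38) and Cxcr3 (-3.38 ± 0.24) with lower values.

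Cell cycle genes were higher in re-tolerized cells: 18 of 27 rose and 0 fell (22 and 1 adjusted over the list alone), with a median of 0.73 (adjusted p = 4.4e-09, adjusted p = 0.14 with an estimated correlation), among them Cdk1 (0.93 ± 0.12), Rrm1 (1.01 ± 0.15) and Aurka (0.97 ± 0.16). Of the inhibitory receptors, 6 of 13 rose and 0 fell (6 and 0 adjusted over the list alone), with adjusted p = 6.4e-05 for the list and adjusted p = 0.14 with an estimated correlation. Among them were Nrp1 (2.11 ± 0.23) and Cd200 (1.08 ± 0.19) besides Lag3 and Ctla4. Anergy and TCR-induced regulators shifted up (adjusted p = 0.021, adjusted p = 0.14 with an estimated correlation): 8 of 23 rose and 4 fell (9 and 4 adjusted over the list alone). Dusp6 (1.65 ± 0.15), a phosphatase of ERK, Izumo1r (1.16 ± 0.12) and Egr2 (1.92 ± 0.21) were higher. Glycolysis genes shifted up (adjusted p = 0.021, adjusted p = 0.14 with an estimated correlation). Examples were Tpi1 (0.68 ± 0.11), Pkm (1.01 ± 0.18) and Hk2 (1.20 ± 0.22). Cholesterol synthesis genes shifted up (adjusted p = 0.0087, adjusted p = 0.14 with an estimated correlation). Examples were Dhcr7 (0.73 ± 0.11) and Cyp51 (0.93 ± 0.15). With the block the medians were 0.65 for the cell cycle (adjusted p = 6.8e-09), 0.43 for inhibitory receptors (adjusted p = 0.0022), 0.46 for glycolysis (adjusted p = 0.036) and 0.18 for cholesterol synthesis (adjusted p = 0.056), and 2, 3, 0 and 0 of their genes passed. With an estimated correlation the first 3 had an adjusted p of 0.17.

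Interferon-stimulated genes shifted down (adjusted p = 9.6e-06, adjusted p = 0.14 with an estimated correlation): 0 of 25 rose and 10 fell (1 and 12 adjusted over the list alone). Among them were Usp18 (-1.77 ± 0.14), Irf7 (-1.25 ± 0.16), Ifit3 (-1.50 ± 0.22), and Oas2 (lower by at least 3.84-fold). Naive and central memory genes shifted down (adjusted p = 3.9e-05, adjusted p = 0.056 with an estimated correlation): 1 of 17 rose and 10 fell (2 and 11 adjusted over the list alone). Klf3 (-1.94 ± 0.21) and Klf2 (-1.12 ± 0.14) were lower. Of the cytokine receptors, 0 of 19 rose and 8 fell (0 and 8 adjusted over the list alone), with adjusted p = 9.6e-06 for the list. Among them were Ifngr1 (-2.10 ± 0.14) and Il18rap (lower by at least 2.24-fold). Of the cytotoxic and effector molecules, 4 of 19 rose and 6 fell (4 and 8 adjusted over the list alone), with adjusted p = 0.085 for the list. Ccl5 (-2.68 ± 0.16), Ctsw (-1.32 ± 0.16) and Gzmm (-2.13 ± 0.26) were lower and Ccl3 higher (0.74 ± 0.09). With the block, interferon-stimulated genes stayed lower (median -0.60, adjusted p = 2.7e-08, adjusted p = 0.16 with an estimated correlation), and 4 of 25 genes passed. The class II genes shifted up (adjusted p = 0.0087, adjusted p = 0.30 with an estimated correlation): 4 of 8 rose and 0 fell (6 and 0 adjusted over the list alone), with H2-DMa (1.26 ± 0.21). Among the markers of CD4 and regulatory T cells, 4 of 10 rose and 1 fell (5 and 2 adjusted over the list alone), with adjusted p = 0.021 for the list and adjusted p = 0.14 with an estimated correlation, with Ikzf2 (1.63 ± 0.18). The myeloid markers (adjusted p = 0.80) and B cell markers (adjusted p = 0.46) did not pass as lists, but with the block the B cell list shifted up (median 0.57, adjusted p = 4.8e-04, adjusted p = 0.17 with an estimated correlation), with 0 of 10 genes passing. Of the 11 lists that passed with the block, 1 (cytokine receptors) passed with an estimated correlation.

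Egr1 (1.31 ± 0.21) rose in re-tolerized against tolerant cells and Tbx21 (-1.93 ± 0.17) fell. Tob1 (-0.52 ± 0.11) lost its call without re-tolerized 1 (adjusted p = 0.085). No difference passed in Pdcd1 (0.15 ± 0.12, adjusted p = 0.44), Eomes (-0.91 ± 0.39, adjusted p = 0.11), Gata3 (-0.45 ± 0.18, adjusted p = 0.086), Ifng (-0.42 ± 0.14, adjusted p = 0.052) and Il2rb (-0.37 ± 0.15, adjusted p = 0.091), or in Cd44 (0.51 ± 0.28, adjusted p = 0.23). Eomes passed without rescued 4 or re-tolerized 2 (adjusted p = 0.020 to 0.021), Gata3 without re-tolerized 2 (adjusted p = 0.0030), Ifng without memory 2, memory 3, tolerant 1 or rescued 4 (adjusted p = 0.022 to 0.041) and Il2rb without memory 3 (adjusted p = 0.0496). In all, 2161 genes passed (1122 higher, 1039 lower), 432 by at least 2-fold, and in 2146 the groups did not overlap, as in 48.3% of all genes (20% by chance). With the shift as a block 33 of the 46 named genes that passed kept their call. The count was 1399 without tolerant 1, 974 without re-tolerized 1, and 1082 with the myeloid and class II covariates, which kept the call of 37 named genes.

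Rescued and memory cells were set side by side as cells that had divided and regained function and cells that had never lost it. The largest rises in rescued cells were in Ltf (4.02 ± 0.58), Lcn2 (3.65 ± 0.52), Camp (3.61 ± 0.55) and Ngp (3.45 ± 0.43) (n = 4 and 3), genes of neutrophil granules, and the largest falls in Sdcbp2 (-2.59 ± 0.09), Stx1a (-2.25 ± 0.35), Actn2 (-2.10 ± 0.15) and Tmie (-1.99 ± 0.19). Stx1a belongs to the genes plotted for the memory 3 shift. Of the cell cycle genes, 21 of 27 rose and 0 fell (21 and 1 adjusted over the list alone), with adjusted p = 9.0e-18 for the list and adjusted p = 0.085 with an estimated correlation, and of the NK-type receptors, 8 of 13 rose and 0 fell (9 and 0 adjusted over the list alone), with adjusted p = 1.2e-08 for the list. Klre1 (3.11 ± 0.18) and Klra7 (1.15 ± 0.09) were higher. Interferon-stimulated genes shifted up (adjusted p = 8.8e-09, adjusted p = 0.14 with an estimated correlation). Examples were Isg15 (1.58 ± 0.19) and Ifit3 (1.53 ± 0.19). Anergy and TCR-induced regulators shifted up (adjusted p = 0.025, adjusted p = 0.21 with an estimated correlation). Ndrg1 (at least 2.36-fold) was higher. Myeloid markers shifted up (adjusted p = 1.2e-08, adjusted p = 0.23 with an estimated correlation). B cell markers shifted down (adjusted p = 2.2e-04, adjusted p = 0.23 with an estimated correlation), but not with the block (median -0.30, adjusted p = 0.096). The NK and gamma-delta T cell markers shifted up (adjusted p = 0.025, adjusted p = 0.23 with an estimated correlation).

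Il2rb (1.00 ± 0.12) and Lag3 (at least 2.30-fold, log2 1.39 ± 0.26) rose and Ctla4 (-1.33 ± 0.19) and Ifng (-1.10 ± 0.12) fell in rescued against memory cells. Eomes (1.10 ± 0.32) lost its call without each memory array, rescued 1, rescued 2 or rescued 3 (adjusted p = 0.066 to 0.12). Egr1 (0.61 ± 0.18) lost it without each memory array or rescued 1 (adjusted p = 0.059 to 0.11). No difference passed in Pdcd1 (0.06 ± 0.10, adjusted p = 0.78), Tbx21 (0.27 ± 0.15, adjusted p = 0.26), Gata3 (0.06 ± 0.15, adjusted p = 0.83), Egr2 (0.46 ± 0.18, adjusted p = 0.097), Tob1 (-0.04 ± 0.09, adjusted p = 0.85) and Il7r (-0.56 ± 0.20, adjusted p = 0.070), or in Cd44 (-0.15 ± 0.24, adjusted p = 0.73), and Il7r passed without rescued 4 (adjusted p = 0.032). In all, 1567 genes passed (654 higher, 913 lower), 264 by at least 2-fold, and in 1314 the groups did not overlap, as in 21.1% of all genes (5.71% by chance). The count was 490 with the shift as a block, 88 against memory 3 alone (assumed to vary like the other groups), 907 without memory 1, 689 without memory 2 and 88 with the myeloid and class II covariates. Of 19 named genes that passed, 5 kept their call against memory 3 alone and 7 with the covariates, where Eomes came to -0.0014. Median scaling gave 430 higher and 391 lower.

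Between re-tolerized and memory cells, Lag3 rose most (at least 33.8-fold, log2 5.27 ± 0.32, n = 2 and 3), followed by Nrn1 (4.72 ± 0.13), Tubb2b (4.31 ± 0.36) and Xcl1 (4.26 ± 0.20), and the largest falls were in Il18r1 (-4.47 ± 0.28), Cxcr3 (-4.39 ± 0.15), Gzmm (-4.08 ± 0.26) and Aqp9 (-4.06 ± 0.16). Cell cycle genes were higher: 25 of 27 rose and 1 fell (25 and 1 adjusted over the list alone), with adjusted p = 4.8e-21 for the list. Examples were Cdk1 (2.38 ± 0.12) and Cdca3 (2.65 ± 0.14). Of the inhibitory receptors, 7 of 13 rose and 1 fell (8 and 1 adjusted over the list alone), with adjusted p = 5.1e-04 for the list and adjusted p = 0.16 with an estimated correlation. Tnfrsf9 was higher (3.82 ± 0.30). Anergy and TCR-induced regulators shifted up (adjusted p = 0.026, adjusted p = 0.16 with an estimated correlation). Rgs16 (at least 8.92-fold) was higher. Cytotoxic and effector molecules shifted down (adjusted p = 0.0083, adjusted p = 0.16 with an estimated correlation). Ccl5 (-3.37 ± 0.16) and Fasl (-2.06 ± 0.13) were lower. Cytokine receptors (adjusted p = 2.5e-04) and chemokine receptors and adhesion molecules (adjusted p = 2.5e-04) shifted down, with 10 of 19 and 12 of 20 lower. Interferon-stimulated genes shifted down (adjusted p = 0.021, adjusted p = 0.45 with an estimated correlation). B cell markers shifted down (adjusted p = 3.4e-04, adjusted p = 0.24 with an estimated correlation). Markers of CD4 and regulatory T cells shifted up (adjusted p = 0.031, adjusted p = 0.15 with an estimated correlation).

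Egr2 (3.19 ± 0.21), Egr1 (3.00 ± 0.21) and Ctla4 (1.76 ± 0.23) rose and Il7r (-3.92 ± 0.23), Tbx21 (-2.53 ± 0.17) and Ifng (-1.43 ± 0.14) fell in re-tolerized against memory cells. Gata3 (-0.83 ± 0.18) lost its call without re-tolerized 1 (adjusted p = 0.054), and Tob1 (-0.45 ± 0.11) lost it without re-tolerized 1 (adjusted p = 0.13). The test was not passed by Pdcd1 (0.31 ± 0.12, adjusted p = 0.071), Eomes (-0.87 ± 0.39, adjusted p = 0.10) and Il2rb (-0.03 ± 0.15, adjusted p = 0.91) or by Cd44 (-0.60 ± 0.28, adjusted p = 0.13). Eomes passed without rescued 4 or re-tolerized 2 (adjusted p = 0.015 to 0.017), Pdcd1 without memory 3 or re-tolerized 2 (adjusted p = 0.0099 to 0.040) and Cd44 without re-tolerized 1 (adjusted p = 0.034). In all, 3249 genes passed (1674 higher, 1575 lower), 908 by at least 2-fold, and in 3184 the groups did not overlap, as in 49.5% of all genes (20% by chance). Against memory 3 alone, with the same assumption, the count was 1213.

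A set of tolerance-associated genes was formed from those that changed in the same direction in tolerant against naive and against memory cells. It held 361 genes, 292 higher and 69 lower in tolerant cells. Among them were Xcl1, Birc5, Mcm10, Cdca3 and Lag3. Independent lists (these are not) would share 36.9 and 21.6, and 81 genes changed oppositely. In 20 simulations with no effect the log2 differences correlated by r = 0.50 through the shared tolerant arrays. No gene passed in both, so they do not gauge this overlap, and 3 tolerant arrays are too few to split.

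In re-tolerized against rescued cells the median change of this set was 0.89 towards the tolerant state (quartiles 0.39 and 1.39), on arrays outside the comparisons that chose the genes, though their spread entered the fit. Of the 361 genes, 274 passed towards and 27 away from the tolerant state (fry, adjusted p = 6.7e-08). In rescued against tolerant cells the median was -0.40 (quartiles -0.73 and -0.17), with 12 genes passing towards and 197 away (fry, adjusted p = 5.2e-06), and with the memory 3 shift as a block the median was -0.44, with 3 and 16 passing. The medians of the 292 genes higher and 69 lower in tolerant cells were 0.97 and 0.36 in the first comparison and -0.46 and -0.12 in the second. The second comparison shares the tolerant arrays with the choice of the genes, and both medians share the rescued arrays. With sets chosen on 2 tolerant arrays and measured on the third, the medians were -0.29 on tolerant 1, -0.37 on tolerant 2 and -0.64 on tolerant 3. Fry tests only whether the genes move one way on balance, not more than other genes. Re-tolerized cells lay past tolerant ones (median 0.42, 172 genes passing further and 32 back). Against memory the median was 0.39 in rescued and 1.16 in re-tolerized cells.

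Marker lists of other cell types differed between arrays of the same group. The mean log2 intensity of the 16 measured myeloid markers was 8.52 to 9.91 in the 4 rescued arrays and highest in rescued 1, against 6.77 to 7.84 in all others. The mean of the 8 class II genes was 9.08 to 9.40 in memory arrays, 8.40 to 9.61 in rescued, 8.39 and 8.46 in re-tolerized, 7.24 to 7.50 in tolerant and 6.82 to 6.95 in naive arrays. The mean of the 10 B cell markers was 7.23 to 7.72 in memory and 6.26 to 6.30 in naive arrays. Of the erythroid and platelet markers, 1 of 9 rose in tolerant against naive cells (Hba-a1) and 3 in rescued against memory cells, and the list passed in no comparison (adjusted p = 0.42 and adjusted p = 0.086 in these). Of the sex-linked genes, 0 of 4 rose and 0 fell (0 and 0 adjusted over the list alone) in tolerant against naive cells. Xist and the Y-linked genes of this list move apart with sex, so its list test shows nothing.

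**Figure D5:**
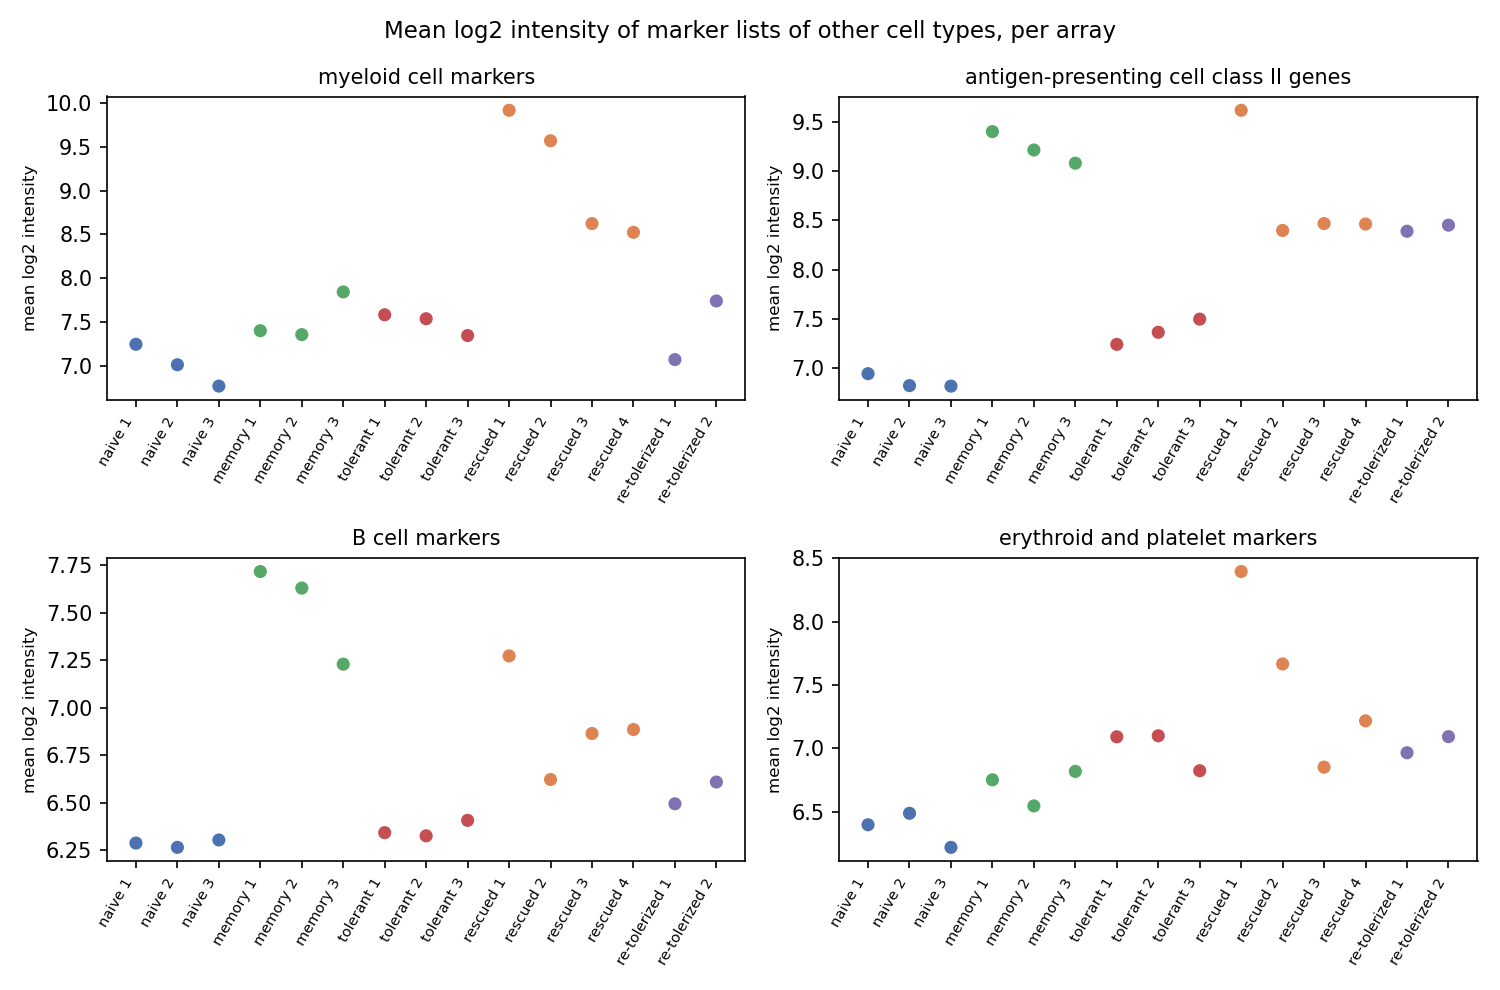
Mean log2 intensity (y axis) of 4 marker lists of other cell types on each of the 15 arrays (x axis), 1 point per array coloured by group. Myeloid markers were highest in rescued 1 (9.91) and rescued 2 (9.57).

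TCR signalling genes passed as a list in no comparison (adjusted p = 0.39 to 0.87), nor did immediate-early and heat-shock genes (adjusted p = 0.18 to 0.98). In re-tolerized against rescued cells, of the TCR signalling genes 5 of 24 rose and 6 fell (6 and 8 adjusted over the list alone). The costimulatory receptor gene Icos was higher (1.65 ± 0.18) and Malt1, an adaptor of NF-kappaB activation, lower (-0.91 ± 0.14). Glycolysis genes passed as a list only in re-tolerized against tolerant cells, and in tolerant against naive cells 3 of 15 rose and 0 fell (4 and 1 adjusted over the list alone), with adjusted p = 0.055 for the list. Tpi1 (1.35 ± 0.10) and Hk2 (1.77 ± 0.20) were higher. The respiratory chain did not pass as a list in tolerant against naive cells (adjusted p = 0.29), where 0 of 29 rose and 0 fell (0 and 0 adjusted over the list alone).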

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

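The tests of memory 3 as a mislabelled or mixed sample, of probes above background, and of myeloid and B cells were chosen after the results were seen. The splits of the arrays and the receptor-probe test were chosen before their outcomes were seen, the latter after the shift itself. A requirement on B cell calls in the class II test of re-tolerized cells was added after its first outcome.

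Single arrays were compared within the 4 rescued arrays by the gap of the highest or lowest log2 value to its neighbour over the range (Dixon's 95% limit), which chance exceeds in about 1 in 20 groups. Of 176 named genes and list means, 11 exceeded it. Rescued 1 stood apart for Dusp6 (10.4, others up to 10.10), the cholesterol synthesis mean (7.89, others up to 7.77), H2-Eb1 (10.8, others up to 9.01) and the class II mean (9.61, others up to 8.47). Rescued 2 was low for Icos (8.52, others from 8.93) and the naive and central memory mean (10.1, others from 10.28). Rescued 3 was high for Ccl5 (14.4, others up to 14.15) and low for Lef1 (7.92, others from 8.10). Rescued 4 was low for Eomes (7.63, others from 8.91) and high for H2-DMa (10.7, others up to 10.20) and Isg15 (11.02, others up to 10.81).

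Over 81 genes that set rescued apart from memory and re-tolerized arrays, memory 3 moved by a median of 24.7% of the way (quartiles 5.89% and 35.97%). This argues against a rescued sample under the memory label behind its 631 genes. A mixture would move both sets alike, but on the linear scale memory 3 moved by 92.2% (80.8% to 101%) over 159 genes apart between the other 6 and 8 arrays, against 11.6% (2.41% to 23.9%) over the 81. Memory 3, rescued 4 and re-tolerized 1 had fewer probes above background than each of the 8 arrays. Over 1395 genes that set these 3 apart from the 8, the 4 others of the 7 moved by a median of 68.01% (quartiles 30.6% and 99.8%). These genes include the 631 in which all 7 lie beyond the 8, so this median is in part built in. It does not decide whether fewer probes above background are the cause. On receptor probes, whose genes T cells do not express, memory 3 correlated less negatively with the 6 rescued and re-tolerized arrays than with the 8 others (mean r -0.0370 and -0.0940, difference 0.0570, against -0.148 and -0.129 for memory 1 and 2), so a shared array or labelling batch is a candidate explanation. The design gives memory 3 no biological difference from memory 1 and 2, so none was tested.

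The myeloid genes higher in rescued arrays rose and fell together over these arrays (median pairwise r = 0.945 over 66 pairs of 12 genes), and myeloid cells or their RNA are a candidate source, at levels of 13.14 for S100a8, 12.03 for S100a9 and 10.07 for Lyz2 (log2, group means). The CD8 sort should remove such cells. The batch shared with memory 3 is argued against, since these genes lay higher in rescued arrays by a median of 2.43 than in the re-tolerized arrays and memory 3 (12 of 12 above 0, 0.0880 to 3.41). Of the 16 list genes, 9 were above the limit on every naive array and 0 are in another list. Expression by rescued T cells themselves was not tested and stays open.

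For class II genes in memory cells, 8 of 10 B cell genes rose too, so B cells or their RNA are a candidate source, with levels of 8.09 for Cd79a and, outside the list, 10.29 for Fcmr, although the CD8 sort should remove them. For class II genes in re-tolerized cells the lowest class II rise, as a share of the rise from naive to memory, minus the highest B cell one was -17.8 percentage points. The shares overlap (class II 8.496% to 45.3%, B cell -3.06% to 26.3%) and 0 of 8 B cell genes passed, though with the memory 3 shift as a block their list shifted up (adjusted p = 4.8e-04, adjusted p = 0.17 with an estimated correlation), so B cells and expression by the T cells cannot be told apart. Of the 8 class II genes, 4 were above the limit on every naive array and 0 are in another list, and of the 10 B cell genes 1 and 1. Activation of the memory and re-tolerized T cells themselves was not tested.

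Other splits of the arrays gave fewer genes than the real groups. For rescued against tolerant the count was 1867 (highest other 595) and against memory 1567 (highest other 222). In each, 1 of 35 splits, the real one, gave a count as large. That share is under 0.05 but not adjusted over the 5 comparisons, and no lower share is possible with 35 splits. For tolerant against naive (1078, highest other 2), tolerant against memory (1061, 0) and memory against naive (1329, 0), it was 1 of 10, too few splits for a share under 0.05. In tolerant against naive, the 3 other splits that part every number gave 0 genes, and the other 6 part only 1 number.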

How the results depend on the processing

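The fits with the memory 3 shift as a block, within each side of it, with myeloid and class II covariates, with only rescued 3 and 4, with a 2-fold set and with dim probes at their bounds were chosen after the results were seen. Unless stated, the cause of a change was not tested.

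Cyclic loess, the authors' normalized values, a normexp offset of 16, no or a stricter filter on dim probes, the mean of all probes and eBayes with trend and robust left every count of the 8 comparisons within 1.5 times. No background correction gave the same values as the authors' normalized ones. Slides are not given, so slide as a block was not run. Of the named genes' values under alternatives fixed beforehand, 9978 kept their direction and side of the threshold, 97 no longer passed, 50 newly passed and 0 reversed, and under the added ones these counts were 1190, 182, 9 and 13.

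A 2-fold minimum lowered the counts by construction, to 255, 248, 290, 297, 595, 432, 264 and 908 genes in the order of the next paragraph. Median scaling gave 1234 in rescued against tolerant and 821 in rescued against memory. Only the 2 groups compared gave 1953 in tolerant against naive and 639 in rescued against memory. Array weights, lowest for memory 3 (0.282) and rescued 4 (0.284), gave 2436 in tolerant against naive, 1994 in tolerant against memory, 2508 in memory against naive and 2769 in rescued against memory.

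Leaving out 1 array gave 751 to 1278 in tolerant against naive, 654 to 1249 in tolerant against memory, 902 to 1515 in memory against naive, 1177 to 2174 in rescued against tolerant, 1420 to 2762 in re-tolerized against rescued, 974 to 2508 in re-tolerized against tolerant, 689 to 1907 in rescued against memory and 2194 to 3579 in re-tolerized against memory. Without a re-tolerized array, the lone one left is assumed to vary like the other groups. The number as a block gave 1328, 1302, 1641, 1789, 2882, 2720, 1526 and 3684 genes in the same order. With this block Egr1 no longer passed in rescued against memory (adjusted p = 0.0502), while Gata3 in rescued against tolerant, Eomes in re-tolerized against tolerant and against memory and Il7r in rescued against memory did (adjusted p = 0.0498, 0.019, 0.016 and 0.0055). It changed no other call of a named gene and no count beyond 1.5 times. Outside tolerant against naive the r of equal numbers lay between -0.142 and 0.463, and 7 of 15 arrays correlated best with an array of their own number.

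The memory 3 shift as a block gave 58 in rescued against tolerant, 246 in re-tolerized against tolerant and 490 in rescued against memory. It reversed Anks3 (0.13) and Pde1b (0.088) in rescued against tolerant. These comparisons cross the shift, so the block removes signal shared with memory 3 and precision (not told apart). Within each side of the shift the counts were 2113 in tolerant against naive, 1480 in tolerant against memory, 1682 in memory against naive, 1709 in re-tolerized against rescued, and, against memory 3 alone, 88 in rescued and 1213 in re-tolerized arrays. The last fits have fewer arrays, and the lone memory 3 is assumed to vary like the other groups.

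The covariates gave 409 in tolerant against memory, 265 in memory against naive, 326 in rescued against tolerant, 1137 in re-tolerized against rescued, 1082 in re-tolerized against tolerant and 88 in rescued against memory. Camp, Ltf, S100a9 and H2-Eb1 are part of these covariates. They reversed Cd79a (0.17), Ctla4 (0.23), H2-Eb1 (0.071) and Sqle (0.052) in tolerant against memory, Cd79a (-0.49), Ctla4 (-0.30) and Fcmr (-0.30) in memory against naive, Camp (-0.33), Ltf (-0.52) and S100a9 (-0.20) in rescued against tolerant and Eomes (-0.0014) in rescued against memory. Only rescued 3 and 4 gave 1019 in rescued against memory.

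The tolerance-associated set, chosen anew in each alternative, kept its direction and fry call wherever fry was run. Medians were 0.58 to 1.44 in re-tolerized against rescued and -1.09 to -0.20 in rescued against tolerant cells (0.75 to 1.06 and -0.53 to -0.36 leaving out 1 array). With dim probes at their bounds they were 0.89 and -0.40. Of the 64 list shifts of the 6 main comparisons that passed with the preset correlation, 26 passed with an estimated one. Signal over background limits what can be seen: 6661 genes were too dim to test.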

Other observations

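Some genes of lists that did not pass in re-tolerized against rescued cells passed alone. The glycolysis genes Tpi1 (1.11 ± 0.10), Pkm (1.17 ± 0.17), Hk2 (1.47 ± 0.21) and Gapdh (0.62 ± 0.10) and the cholesterol synthesis genes Sqle (1.24 ± 0.20), Cyp51 (0.94 ± 0.14) and Dhcr7 (0.56 ± 0.11) rose in re-tolerized cells. In these lists, 6 of 15 rose and 3 fell (6 and 4 adjusted over the list alone) for glycolysis (adjusted p = 0.27) and 6 of 15 rose and 1 fell (6 and 1 adjusted over the list alone) for cholesterol synthesis (adjusted p = 0.059). The death-promoting genes Dapk2 (-2.78 ± 0.11) and Bbc3 (-1.40 ± 0.14) fell, while of the apoptosis regulators 4 of 21 rose and 4 fell (5 and 7 adjusted over the list alone), with an adjusted p of 0.19 for the list.

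Sex-linked genes differed between arrays of 1 group. The log2 level of Xist was 8.89 in naive 2 against 5.82 and 6.04 in naive 1 and 3, and 5.92 in tolerant 1 against 9.07 and 9.996 in tolerant 2 and 3. It was 7.08 to 9.59 in memory arrays, up to 7.67 in rescued and up to 6.35 in re-tolerized arrays. Eif2s3y, on the Y chromosome, was 9.52 and 10.08 in naive 1 and 3 and 5.93 in naive 2.

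Rescued 4 and re-tolerized 1 had the highest mean raw intensity on receptor probes (63.4 and 60.03, others 51.9 to 56.8), and correlated there with r = 0.723 (probes are not independent replicates). Of 863 probes with no symbol that were bright enough to test, 67 to 256 passed per comparison.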
